A study of Rattus norvegicus with 12 samples.

How the data were processed

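The samples were 12 Agilent Whole Rat Genome 4x44K arrays of cortical RNA from Wistar rat pups, 3 pups in each of 4 groups, control or injured by the Rice procedure and given saline or MCI-186. Per the labels' protocols, the cortex on the ligated side was taken, and 500 ng of total RNA was labelled with Cy3 for 1-colour hybridisation. The hypoxia chamber was held at 33 °C, and pups recovered for 1 to 2 h between ligation and hypoxia. Groups and replicate numbers were taken from the labels.

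The deposited scanner files hold spot intensity on a linear scale, background-subtracted and processed by Agilent Feature Extraction 9.5.3.1, per the file headers. The deposited value table holds log2 values, which by comparison with the scanner intensities are the signals over the 75th percentile of each array, with each probe then set to a median of 0 over the 12 arrays. Each of its columns correlated with the recomputed values at 0.999 or more, and column medians lay between -0.12 and 0.12, so scale, centring and direction were settled, and the authors' own method is not given in the sources used here. That table held 41088 probes, 76 of them controls. Each scanner file held 45018 spots, with 70 to 160 outlier spots and at most 1 saturated spot per array. Spike-in slopes lay between 0.90 and 1.00. No pair of arrays held identical values.

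Processed signals were divided by the 75th percentile of each array over spots that were not controls, set to at least 0.005 of it (64950 values) and log2-transformed. Control and outlier spots were left out, which left 160 missing values, and the spots of 1 probe were averaged. Probes were kept where they were well above background on all 3 arrays of at least 1 group (28523 of 41012 probes). No reference genome was used. The scanner files used here give an accession but no symbol, so probes were named through a table of RefSeq accessions of the GRCr8 assembly. Of 16116 curated transcript accessions 15080 matched, and 15184 probes carried one of 12206 symbols, while 25828 stayed unnamed. For each of 2181 genes with several probes 1 probe was used, planned as the one with the highest mean signal. The ranking was misaligned with the probes left after the filter, so the probe used was not always the brightest. With no filter on dim probes the brightest was used. Among these 2181 genes, 10 in the saline arm and 21 in the MCI-186 arm had probes called in opposite directions, and 0 of these are named in the text. The tested features were 9283 genes and 16615 unnamed probes, and log2 changes of a gene near the floor understate its change. Where no probe of a gene was well above background on any array of a group, the fold is given as a bound. It is the mean of the brighter group against, on each array of the dimmer group, the higher of the gene's own signal and the lowest signal that was well above background.

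Differences were tested with limma 3.58.1 in R 4.3.3, with files read in Python 3.11.15. A model of 4 group means was fitted to all 12 arrays, with 8 residual degrees of freedom and 2.51 prior ones, and 5 contrasts were drawn from it. They were injury in saline pups, injury in MCI-186 pups, MCI-186 in injured pups, MCI-186 in controls, and the difference between the injury effects. P values were adjusted by Benjamini-Hochberg over all features of a contrast, with a threshold of 0.05. Each p value from 3 pups against 3 is set against the spread within groups, pooled over the pups of all 4 groups. It holds no spread between slides. Standard errors are limma's moderated ones. Named genes were, for each pairwise contrast, the 10 highest and 10 lowest changes among genes that passed and whose groups did not overlap. Where fewer than 20 passed all were named, and where fewer than 10 did, also the 5 lowest p in each direction. For the interaction 5 in each direction were named, and for each gene list up to 4 members with the lowest p, with other members given as examples of the list's range. A few genes that these rules name are not reported here.

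Gene lists were written before the data were examined. They were immediate early genes, heat shock proteins, endoplasmic reticulum and integrated stress response, hypoxia-inducible genes, antioxidant defence, cytokines with chemokines and adhesion molecules, cell death, cell cycle, extracellular matrix and proteolysis, growth factors and neuropeptides, interferon-response genes, cholesterol synthesis, glucocorticoid-responsive genes and xenobiotic response genes. Cell type lists were microglia and macrophages, neutrophils, T cells, reactive and homeostatic astrocytes, oligodendrocyte progenitors, myelin, excitatory and inhibitory neurons, synaptic and pan-neuronal genes, endothelium, mural cells and fibroblasts, choroid plexus and ependyma, red blood cells and striatum. Of 30 lists 29 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists of a contrast. A list of Y-linked genes had 0 named members on the array. Some genes stand in more than 1 list. No call of any list held when camera estimated the correlation, where adjusted p ran from 0.163 in the injury contrasts and from 0.0772 in the others.

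The fit was tested on simulated data with 200 of 9237 genes changed. Each gene was drawn independently, with 1 spread pooled over all groups, so recovery in comparisons of injured pups may be overstated. The simulation adjusted p over the 9237 genes alone, while the real tests also adjusted over the unnamed probes. Recovery may therefore also be overstated for comparisons with few changes. For injury in saline pups it recovered 44.0%, 82.0%, 100.0% and 100.0% of changes of 1.5, 2, 4 and 8-fold, and for injury in MCI-186 pups 54.0%, 80.0%, 98.0% and 98.0%. For MCI-186 in controls it recovered 62.0% of 1.5-fold and 90.0% of 2-fold changes.

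Alternatives fixed before the data were examined were quantile normalization, the authors' processed values, no filter and a stricter filter on dim probes, the mean of a gene's probes, only the groups of the contrast, eBayes with trend and robust settings, array weights, the replicate number as a block, each array left out in turn, camera with an estimated correlation, and fry. Normexp background correction on median signals and a fit without the least correlated array of each group were chosen after seeing the data. The slide as a block could not be fitted, since each of the 4 slides held 1 group.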

Results

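Gene expression was measured in the cortex of young Wistar rats on 12 single-colour Agilent Whole Rat Genome arrays, 1 array per pup and 3 pups in each of 4 groups. Injury was produced by the Rice model of neonatal hypoxia-ischemia, in which the left common carotid artery is ligated at 7 days of age and the pup then breathes 8% oxygen for 1 h. Injured and control pups received either saline (100 µl) or MCI-186 (edaravone, a free radical scavenger, 9 mg per kg), and injured pups were given a second injection 30 min later. The labels give an age of 2 weeks and no other collection time. Each array held 45018 spots, of which 43379 were not controls, and between 65.1% and 73.7% of these were well above background. The 75th percentile signal lay between 920 and 1258, and the number of arrays limits the precision. Arrays of one group correlated at 0.983 to 0.997. The first principal component held 77.0% of the variance over 25242 probes and placed the 6 control arrays between -63.1 and -55.7 and the 6 injured arrays between 30.4 and 82.1. Each group lay on a slide of its own, so slide and treatment cannot be told apart where MCI-186 is compared with saline, while injury was compared on 2 separate pairs of slides.

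The first comparison asked which genes the injury changed in pups given saline. In the injured cortex, immune, interferon-response and reactive glial genes were many times higher, and genes of neurons and of cholesterol synthesis were lower. Complement component C3 rose by 6.86 ± 0.30 on the log2 scale, the interferon-induced ubiquitin-like protein Isg15 by 6.69 ± 0.30 and osteopontin, Spp1, by 6.32 ± 0.28 (SE, n = 3 pups per group, limma adjusted p = 6.94e-07 for each). The neurofilament genes Nefh and Nefm fell by 1.60 ± 0.28 and 1.60 ± 0.29, with limma adjusted p of 0.00137 and 0.00164. Of 9280 named genes tested, 4931 passed limma's adjusted threshold, 2312 higher and 2619 lower. Changes of at least 2-fold were mostly increases, with 1266 genes higher and 399 lower, and of at least 8-fold almost all were, with 230 higher and 2 lower. The median change of all named genes was -0.08. A further 7531 probes without a gene name passed, 2775 higher and 4756 lower. The 3 values of one group lay wholly above the 3 of the other for 5809 genes (62.8%), against a chance share of 10%.

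The other large increases in the saline arm, each with all 3 injured pups above all 3 controls, included further immune genes. The monocyte chemokine Ccl2 rose by 6.28 ± 0.30, the interferon-induced chemokine Cxcl10 by 6.37 ± 0.52, the schlafen gene Slfn4 by 6.61 ± 0.58 and Pla2g7, which encodes platelet-activating factor acetylhydrolase, by 6.42 ± 0.30 (limma adjusted p from 1.06e-06 to 2.21e-05). Ccl12 and F10, coagulation factor X, were not well above background in any saline control and were at least 36.8-fold and at least 75.4-fold higher after injury. Transferrin, Tf, was 6.47 ± 1.96 higher (limma adjusted p = 0.0202), but 1 of the 3 saline controls was not well above background, and the adjusted p was 0.0584 without injured saline replicate 3. Without saline control replicate 3 it was 3.35 higher (limma adjusted p = 0.00077).

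The largest decreases were smaller and fell on genes of mixed function. The serine protease gene Prss22 fell by 3.46 ± 0.42, tyrosinase, Tyr, by 2.89 ± 0.54, the muscle ring finger gene Trim54 by 2.35 ± 0.29, the potassium channel subunit gene Kcns1 by 2.31 ± 0.31, the olfactory receptor gene Olr59 by 2.28 ± 0.45 and the copine gene Cpne9 by 2.27 ± 0.38 (limma adjusted p from 0.00017 to 0.00258). C14h1orf146, granzyme C (Gzmc), Fkbp6 and the olfactory receptor gene Or2w6 were not well above background in any injured saline pup. They were at least 2.59-fold, 2.28-fold, 1.5-fold and 2.09-fold lower there than in saline controls, with Fkbp6 well above background in 2 of the 3 controls.

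Immune genes rose as groups. Of 24 measured microglia and macrophage markers, 22 rose and 2 did not pass. Those that rose included the lysosomal genes Gpnmb (5.65 ± 0.25) and Cd68 (5.43 ± 0.27), and the antigen presentation gene Cd74 (4.03 ± 0.23). The pan-leukocyte gene Ptprc was 1.38 higher at 1 probe. At its other 2 probes it was 3.69 and 3.54 higher, but these were not well above background in controls, so these are not measured sizes. Adjusted over the list alone, 23 rose, the median change was 3.17, and limma's camera gave adjusted p = 4.37e-18, but adjusted p = 0.176 with an estimated correlation. Of 20 cytokines, chemokines and adhesion molecules, 18 rose and 1 fell, the neuronal chemokine Cx3cl1 (-1.11), with the same counts adjusted over the list alone. Ccl3 rose by 5.36 ± 0.23, the adhesion molecule Icam1 by 2.68 ± 0.15 and Tgfb1 by 2.60 ± 0.16, and limma's camera gave adjusted p = 1.28e-13, with adjusted p = 0.176 with an estimated correlation. Of 20 interferon-response genes, 19 rose, and 19 adjusted over the list alone, with a median of 3.82. They included the antiviral sensor Oas1a (5.74 ± 0.32), the peptide transporter Tap1 (3.92 ± 0.25) and the regulator Irf7 (5.79 ± 0.36), and limma's camera gave adjusted p = 2.53e-17, with adjusted p = 0.176 with an estimated correlation.

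Markers of circulating leukocytes rose in the same arm. Of 8 T cell markers, 6 rose and 1 fell, also adjusted over the list alone, with Cd4 and Cd8a at least 7.33-fold and at least 8.56-fold higher, Cd6 1.80 ± 0.26 higher and Cd8b 3.30 ± 0.67 higher. The list passed limma's camera at adjusted p = 0.00388, with adjusted p = 0.176 with an estimated correlation and 0.208 with the stricter filter on dim probes. Of 7 neutrophil markers, 5 rose, also adjusted over the list alone, led by lipocalin 2, Lcn2 (5.33 ± 0.45), which reactive astrocytes also express, with Csf3r at least 7.35-fold higher (limma's camera adjusted p = 0.00765, and adjusted p = 0.281 with an estimated correlation). The neutrophil median of 1.83 was 0.93 without injured saline replicate 3, whose mean for this list was 3.56 against 1.54 and 1.64 in the other 2 pups. The calcium-binding S100a8 (2.66 ± 0.91) and Padi4 (1.47 ± 0.49) lost their call without that pup, at 1.43 and 0.93 with limma adjusted p of 0.082 and 0.108. Their calls were also lost without saline control replicate 1 (0.0881 and 0.0865) or 3 (0.0938 and 0.0786), and that of Padi4 without injured saline replicate 2 (0.0669). The 6 measured red blood cell genes moved the other way without passing, from -1.27 for Hbb to -0.45 for Slc4a1 with Alas2 at -1.02, Ahsp at -0.62 and Hbb-b1 at -0.53 between them (limma's camera adjusted p = 0.393).

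Reactive astrocyte, matrix and proliferation genes also rose with injury in saline pups. Of 16 reactive astrocyte genes 14 rose, also adjusted over the list alone, including the intermediate filament Gfap (4.53 ± 0.20), the hyaluronan receptor Cd44 (4.00 ± 0.20) and Aspg (3.82 ± 0.21), with limma's camera adjusted p = 2.01e-10 and adjusted p = 0.176 with an estimated correlation. Extracellular matrix and proteolysis genes rose in 11 of 12 cases, also adjusted over the list alone. The protease inhibitor Timp1 rose by 2.96 ± 0.25, urokinase Plau by 3.42 ± 0.29, tissue plasminogen activator Plat by 1.32 ± 0.19 and Mmp2 by 1.10 ± 0.13 (limma's camera adjusted p = 7e-07, and adjusted p = 0.176 with an estimated correlation). Of 18 cell cycle genes 15 rose and 1, Ccne1, fell, with 17 higher and 1 lower adjusted over the list alone. The replication licensing genes Mcm2 and Mcm6 rose by 1.77 ± 0.20 and 1.12 ± 0.17, Cdk1 by 1.58 ± 0.27 and Ccnd1 by 0.99 ± 0.16, and limma's camera gave adjusted p = 1.59e-06, with adjusted p = 0.281 with an estimated correlation.

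Markers of neighbouring tissues moved with these groups. Of 13 mural cell and fibroblast markers 9 rose and 3 fell, the same adjusted over the list alone, with the collagens Col3a1 (2.28 ± 0.20), Col1a2 (1.34 ± 0.18) and Col1a1 (1.95 ± 0.29) and the peptidase Anpep (1.37 ± 0.17) higher (limma's camera adjusted p = 0.00328, and adjusted p = 0.226 with an estimated correlation). Of 7 choroid plexus and ependyma markers 6 rose, and 7 adjusted over the list alone, with a median of 2.16. The ciliary regulator Foxj1 rose by 4.24 ± 0.34, the water channel Aqp1 by 1.73 ± 0.26 and Drc12 by 2.92 ± 0.49, while Folr1 was at least 23.4-fold higher (limma's camera adjusted p = 7.56e-05, and adjusted p = 0.181 with an estimated correlation). Of 10 striatum markers, 3 fell and 1 rose, also adjusted over the list alone, and the list did not pass (limma's camera adjusted p = 0.33). The phosphodiesterase gene Pde10a fell by 1.20 ± 0.21 and Gpr6 by 1.52 ± 0.38.

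Neuronal genes fell as lists, and no member of the 3 neuronal lists was called higher. Of 19 synaptic and pan-neuronal genes 16 fell, and 18 adjusted over the list alone, with a mean of -1.01, including the vesicle genes Vamp2 (-0.76 ± 0.14) and Vamp1 (-1.27 ± 0.23). The list had limma's camera adjusted p = 2.16e-05, with adjusted p = 0.363 with an estimated correlation. Excitatory neuron genes fell in 10 of 16 cases, also adjusted over the list alone, with the kinase subunits Camk2a (-0.97 ± 0.21) and Camk2b (-1.02 ± 0.24), the glutamate receptor Gria3 (-0.86 ± 0.22) and the transcription factor Neurod2 (-0.79 ± 0.21) among them (limma's camera adjusted p = 0.00765, and adjusted p = 0.363 with an estimated correlation). Inhibitory neuron genes fell in 7 of 12 cases, and in 9 adjusted over the list alone. The GABA synthesis gene Gad1 fell by 1.11 ± 0.15, the vesicular transporter Slc32a1 by 1.05 ± 0.17 and Calb1 by 0.86 ± 0.16. That list passed with limma's camera at adjusted p = 0.025, but not with an estimated correlation (adjusted p = 0.363 with an estimated correlation) or quantile normalization (adjusted p = 0.0702).

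Genes of cholesterol synthesis fell, and homeostatic astrocyte genes moved in both directions. Of 17 cholesterol synthesis genes 14 fell, with 14 lower and 1 higher adjusted over the list alone, including Idi1 (-1.19 ± 0.15), Fdps (-1.11 ± 0.16), squalene epoxidase Sqle (-0.95 ± 0.15) and the sterol sensor partner Insig1 (-1.31 ± 0.21). That list passed limma's camera at adjusted p = 0.000132, with adjusted p = 0.36 with an estimated correlation. Homeostatic astrocyte genes rose in 8 of 15 cases and fell in 3, or 4 adjusted over the list alone. The water channel Aqp4 rose by 1.74 ± 0.15 (0.90 to 1.69 at its other 3 probes), Mlc1 by 1.75 ± 0.19 (0.97 at its other probe) and the gap junction gene Gja1 by 1.40 ± 0.15, and the glycolytic Aldoc fell by 0.53 ± 0.08. As a list they passed limma's camera at adjusted p = 0.0425, with adjusted p = 0.221 with an estimated correlation, and between 0.0557 and 0.0615 without saline control replicate 1 or 2 or injured saline replicate 1 or 3. The call was also lost with no filter on dim probes and with the stricter filter (limma's camera adjusted p = 0.0625 and 0.0922). Oligodendrocyte progenitor markers rose in 4 of 8 cases, also adjusted over the list alone, namely Ptprz1 (0.81 ± 0.14), Bmp4 (1.18 ± 0.21), Sox10 (0.43 ± 0.11) and Pdgfra (0.48 ± 0.13). For these markers limma's camera gave adjusted p = 0.0387, with adjusted p = 0.363 with an estimated correlation, 0.0562 without saline control replicate 3 and 0.0589 without injured saline replicate 3. Of 13 myelin genes only Aspa rose (0.85 ± 0.14), also adjusted over the list alone. The others did not pass, with Ermn at -0.86 and Mobp at -0.82, or -1.04 at its other probe (limma's camera adjusted p = 0.939).

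Stress and death genes moved in part. Of 22 antioxidant defence genes 10 rose and 3 fell, with 11 and 3 adjusted over the list alone. Heme oxygenase, Hmox1, rose by 2.62 ± 0.18, metallothionein Mt1 by 2.15 ± 0.26, ferritin light chain Ftl1 by 1.21 ± 0.12 and peroxiredoxin Prdx1 by 0.88 ± 0.13, while the superoxide dismutase gene Sod2 fell by 0.36. The list median was 0.47, or 0.29 without saline control replicate 3, and limma's camera gave adjusted p = 0.0111, with adjusted p = 0.275 with an estimated correlation. Of 24 cell death genes 13 rose and 2 fell, with 15 and 2 adjusted over the list alone, led by the death receptor Fas (3.35 ± 0.31), Casp8 (1.97 ± 0.19), the receptor Tnfrsf1a (1.86 ± 0.20) and the cell cycle inhibitor Cdkn1a (1.40 ± 0.14). Cell death genes had limma's camera adjusted p = 2.69e-05, with adjusted p = 0.226 with an estimated correlation. Of 15 endoplasmic reticulum and integrated stress response genes 6 rose and 1 fell, also adjusted over the list alone, among them Sdf2l1 (1.66 ± 0.20), Trib3 (1.32 ± 0.21), Pdia4 (1.06 ± 0.17) and Creld2 (1.06 ± 0.17). This list passed limma's camera at adjusted p = 0.0363, with adjusted p = 0.281 with an estimated correlation, 0.0746 without saline control replicate 1, with a median of 0.14 in place of 0.24, and 0.0982 without injured saline replicate 1.

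**Figure D1:**
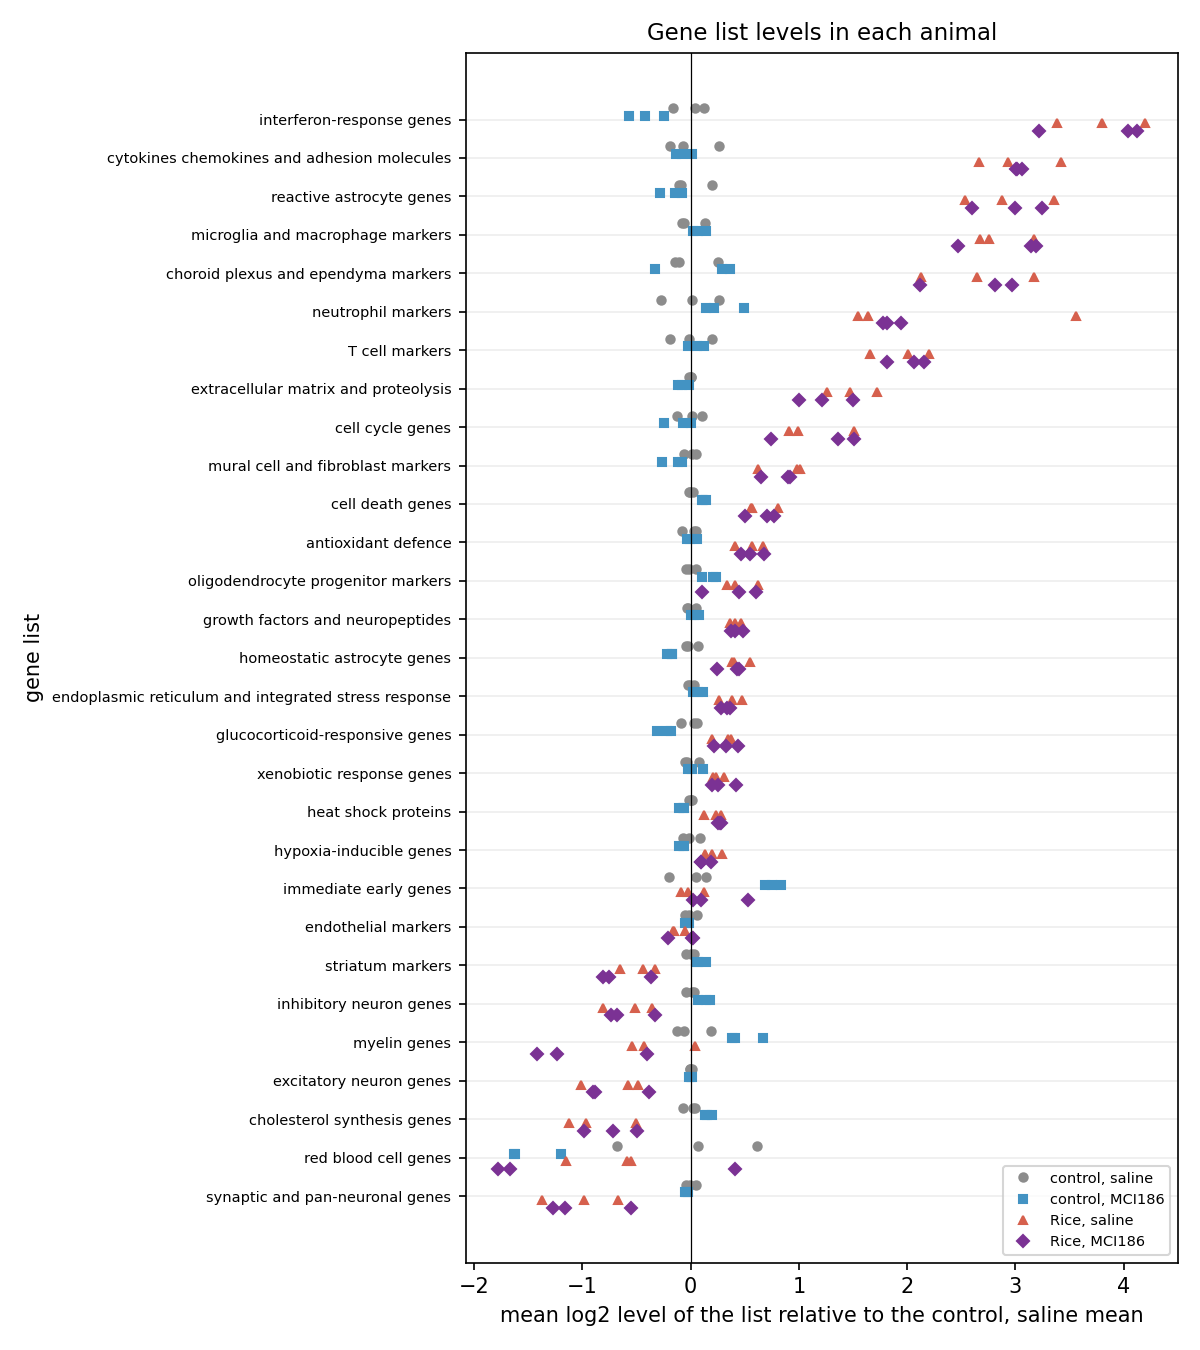
Mean log2 level of each gene list (x axis, relative to the mean of the saline controls) in each of the 12 pups, with 1 symbol per pup, 4 groups by colour and shape, and 29 lists on the y axis. The 6 injured pups lie between 3.22 and 4.20 for interferon-response genes and between -1.38 and -0.55 for synaptic and pan-neuronal genes, and the 6 control pups lie between -0.57 and 0.13 and between -0.05 and 0.05.

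The second comparison asked the same question in pups given MCI-186. The injured cortex again held many times more transcript of immune, interferon-response and reactive glial genes and less of neuronal, cholesterol synthesis and myelin genes. Isg15 rose by 6.76 ± 0.30, Gfap by 4.99 ± 0.20 and C3 by 6.27 ± 0.30, and the myelin gene Mobp fell by 2.58 ± 0.38 (SE, n = 3 pups per group, limma adjusted p from 6.64e-07 to 0.00046). Of 9279 named genes tested with limma, 5104 passed, 2398 higher and 2706 lower, and at 2-fold or more 1315 were higher and 385 lower. At 8-fold or more 221 were higher and 4 lower. Another 8043 unnamed probes passed, 2955 higher and 5088 lower. The 3 values of one group lay wholly above those of the other for 68.6% of genes, against a chance share of 10%.

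Slfn4, Cxcl10, the antiviral GTPase Mx1, the ubiquitin-like Ubd, F10 and Ccl12 were not well above background in any control given MCI-186. They were at least 107-fold, 97.2-fold, 69.5-fold, 28.0-fold, 63.0-fold and 34.1-fold higher in the injured pups. Irf7 rose by 6.48 ± 0.36, with a limma adjusted p of 2.17e-06. The class I histocompatibility gene RT1-CE5 was 6.61 higher at a probe not well above background in these controls (limma adjusted p = 1.99e-05) and just 1.44 higher at its other probe. The largest decreases were of mixed function and included the oligodendrocyte and myelin genes Hapln2 and Klk6. Hapln2, a link protein of myelinated axons, fell by 3.57 ± 0.43, and the oligodendrocyte protease gene Klk6 by 3.36 ± 0.43 (limma adjusted p of 0.000157 and 0.000222). In the saline arm Hapln2 was at -2.08, and at -1.68 at its other probe. Aipl1, a photoreceptor chaperone gene, fell by 4.11 ± 0.47, Cblc by 3.40 ± 0.31, Clca1 by 2.84 ± 0.54, Prss22 by 2.82 ± 0.42 and Tyr by 2.45 ± 0.54 (limma adjusted p from 2.69e-05 to 0.00384). The fall of Aipl1 started from a high level in controls given MCI-186, as it was not well above background in saline controls. Fkbp6 was at least 3.14-fold lower. The hormone gene Fgf21 was at least 1.49-fold lower than in controls, of which 2 of 3 were well above background. Its limma adjusted p of 0.0445 rose above the threshold in 11 of 22 other settings, to 0.136 without control MCI-186 replicate 2, 0.126 without replicate 3 and between 0.0553 and 0.0979 without injured saline replicate 2 or any single saline control or injured MCI-186 replicate.

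The immune lists in the MCI-186 arm had counts close to those of the saline arm. Of 24 microglia and macrophage markers 23 rose, of 20 interferon-response genes all 20 rose and of 20 cytokines, chemokines and adhesion molecules 18 rose and 1 fell, with the same counts adjusted over each list alone. Medians were 3.00, 4.05 and 2.58, limma's camera gave adjusted p of 2.47e-17, 1.76e-17 and 2.24e-13, and each had adjusted p = 0.163 with an estimated correlation. Ccl3 rose by 5.88 ± 0.23 and Oas1a by 5.74 ± 0.32, and Cxcl1 was at least 21.1-fold higher. Ptprc was 1.34 higher at 1 probe, and 3.40 and 3.04 higher at the probes not well above background in controls. Of 8 T cell markers 6 rose and 1 fell, also adjusted over the list alone, with Cd8a at least 10.3-fold and Cd8b at least 22.2-fold higher. T cell markers had limma's camera adjusted p = 0.00672, with adjusted p = 0.163 with an estimated correlation and 0.282 with the stricter filter on dim probes. Of 7 neutrophil markers Lcn2 (5.10 ± 0.45) and Csf3r (2.25 ± 0.78) passed, 1 of them adjusted over the list alone, and the list did not pass (limma's camera adjusted p = 0.0608). Csf3r had a limma adjusted p of 0.0332, and of 0.117 or 0.0976 without control MCI-186 replicate 1 or 2 and 0.1, 0.0533 or 0.0611 without injured MCI-186 replicate 1, 2 or 3. Its log2 change was 1.37 without control MCI-186 replicate 1. Red blood cell genes did not pass, with a median of 0.46 (limma's camera adjusted p = 0.406).

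Reactive astrocyte genes rose in 15 of 16 cases, extracellular matrix genes in 9 of 12 and cell cycle genes in 15 of 18 with 1 lower. Adjusted over each list alone the counts were 15 higher, 10 higher, and 17 higher with 1 lower. These lists had limma's camera adjusted p of 3.24e-11, 2.1e-05 and 5.35e-07, with adjusted p = 0.163, 0.164 and 0.284 with an estimated correlation. Cd44 rose by 4.05 ± 0.20, Timp1 by 2.77 ± 0.25, Ccnb1 by 2.07 ± 0.28 and Ube2c by 1.68 ± 0.24, and Plau was at least 9.33-fold higher. Mural cell and fibroblast markers rose in 9 of 13 cases and fell in 2, and choroid plexus and ependyma markers rose in 6 of 7, with the same counts adjusted over each list alone. Both passed limma's camera, at adjusted p of 0.00227 and 0.000181, with adjusted p = 0.21 and 0.189 with an estimated correlation, and the proteoglycan Ogn rose by 2.73 ± 0.35 (1.06 at its other probe), Foxj1 by 4.03 ± 0.34 and Kcnj13 by 2.01 ± 0.33. The other probe of Ogn was the brighter, and with no filter on dim probes, where it was used, Ogn did not pass (limma adjusted p = 0.11).

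Of 13 myelin genes, 11 fell and 1, Aspa, rose in the MCI-186 arm, also adjusted over the list alone, with a median of -1.86. The structural gene Mobp fell by 2.58 ± 0.38, Opalin by 2.03 ± 0.30 and the cytoskeletal Ermn by 2.36 ± 0.37 (limma adjusted p from 0.00046 to 0.0007). For the list, limma's camera gave adjusted p = 0.00135, with adjusted p = 0.307 with an estimated correlation. Striatum markers fell beside them in 6 of 10 cases, also adjusted over the list alone, with the dopamine receptor Drd1 at -0.71 ± 0.10 and Gpr6 at -2.20 ± 0.38. Their list passed limma's camera at adjusted p = 0.0265, with adjusted p = 0.307 with an estimated correlation and 0.0851 with the stricter filter on dim probes. Oligodendrocyte progenitor markers did not pass as a list (limma's camera adjusted p = 0.578), with 3 members higher and 2 lower, Neu4 and Olig1 (-0.56 ± 0.11), also adjusted over the list alone.

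Neuronal and cholesterol genes fell as in the saline arm. Synaptic and pan-neuronal genes fell in 18 of 19 cases, excitatory neuron genes in 10 of 16, inhibitory neuron genes in 10 of 12 and cholesterol synthesis genes in 14 of 17. Adjusted over each list alone, 18, 10, 11 and 16 fell. Limma's camera gave adjusted p of 7.62e-05, 0.00543, 0.00514 and 0.000114, with adjusted p = 0.348, 0.307, 0.307 and 0.307 with an estimated correlation. Map2 fell by 1.14 ± 0.19, the layer 5 regulator Fezf2 by 0.75 ± 0.17, the neuropeptide Sst by 1.02 ± 0.21 and Mvd by 0.74 ± 0.12. Reln was at -0.86 ± 0.18 at the probe used and at 0.10 at the other, so its direction is not settled. Antioxidant genes rose in 10 of 22 cases and fell in 4, or 11 and 4 adjusted over the list alone, with Hmox1 2.34 ± 0.18 higher and the peroxide-reducing Gpx1 1.71 ± 0.26 higher. Cell death genes rose in 10 of 24 and fell in 1, and homeostatic astrocyte genes rose in 8 of 15 and fell in 3, with 9 and 3 for the latter and the same counts for the former adjusted over the list alone. Limma's camera gave adjusted p of 0.0126, 0.00227 and 0.0168 for these 3 lists, with adjusted p = 0.284, 0.307 and 0.163 with an estimated correlation. The endoplasmic reticulum and integrated stress response list did not pass (limma's camera adjusted p = 0.145), with 3 members higher and 2 lower, also adjusted over the list alone, among them Pdia4 at 1.27 ± 0.17 and the asparagine synthetase gene Asns at -0.50 ± 0.11. Immediate early genes, which did not pass as a list in either arm (limma's camera adjusted p = 0.6 and 0.105), held 5 higher and 3 lower members in the saline arm and 4 higher and 14 lower in this one, also adjusted over the list alone. Atf3 rose by 3.57 ± 0.28 and 2.91 ± 0.28 in the 2 arms and Arc, a marker of neuronal activity, was at -0.75 and -2.28. In the saline arm the list's median of -0.17 differed in sign from its mean of 0.00 and from the upward direction of the test. In the MCI-186 arm the decreases started from a raised control level. Relative to saline controls, the list mean was 0.76 in controls given MCI-186 and 0.22 in injured pups given it.

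The injury effects of the arms were then set side by side. The genes that injury raised or lowered in saline pups moved nearly as far in MCI-186 pups, C3 by 6.86 and 6.27, Gfap by 4.53 and 4.99, and Prss22 by -3.46 and -2.82. Over the 4931 genes called in the saline arm, the regression slope of the MCI-186 arm on the saline arm was 0.963 (r = 0.974 across genes, which are not independent replicates), and 98.9% kept their sign. Over the 5104 called in the MCI-186 arm the slope of the saline arm on the MCI-186 arm was 0.933. Both arms called 4240 genes, 4232 with the same sign and 8 with opposite signs. The slope is lowered by error in the arm that selects the genes, and it ran from 0.897 to 1.07 when single arrays were left out. The arms share no array and no slide.

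**Figure D2:**
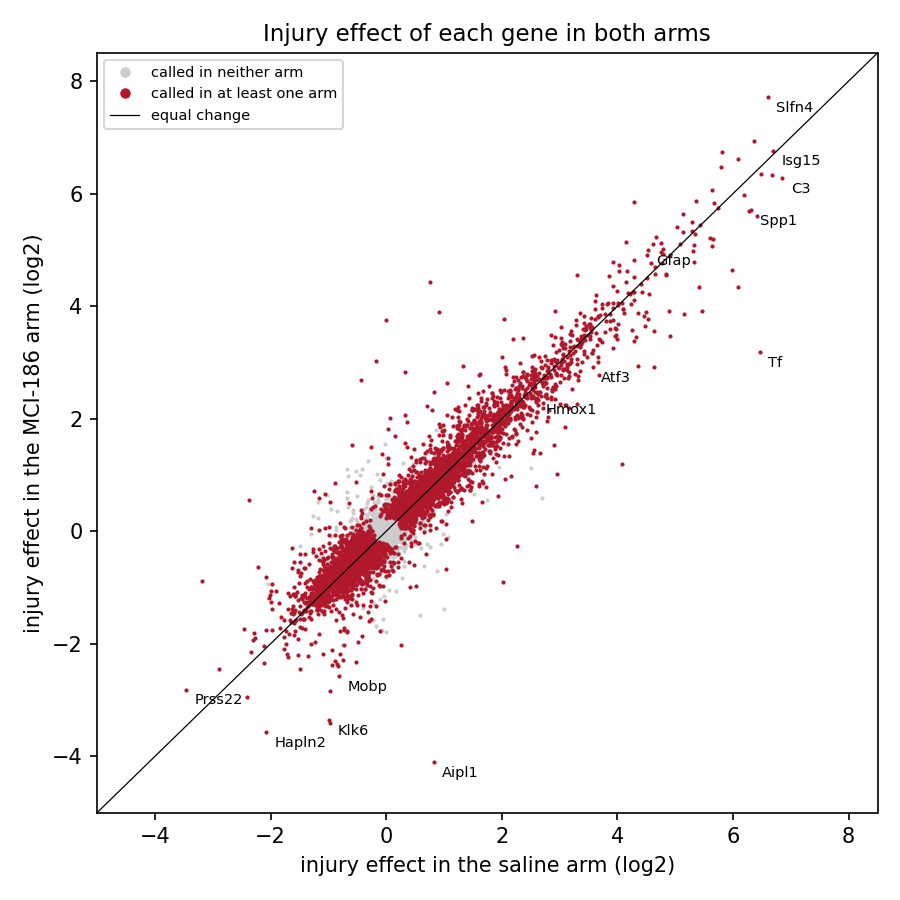
Log2 injury effect of each named gene in the saline arm (x axis) and in the MCI-186 arm (y axis), with red points for genes called by limma in at least 1 arm, grey points for the rest and a line of equal change. Over the 4931 genes called in the saline arm the points follow a slope of 0.963, and Hapln2, Klk6, Mobp and Aipl1 lie below the line.

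The third comparison asked what MCI-186 changed in injured cortex. No named gene of 9279 passed limma's test, with 204 at an unadjusted p under 0.05 and a lowest adjusted p of 0.609, and no unnamed probe passed. Between injured pups given MCI-186 and saline, the mean difference was 0.07 for microglia and macrophage markers, 0.02 for reactive astrocyte genes, 0.00 for interferon-response genes and 0.02 for synaptic genes, and none of these lists passed (limma's camera adjusted p from 0.542 to 0.979). For reactive astrocyte, interferon-response and synaptic genes the direction depended on single pups. Without injured MCI-186 replicate 2, the median was 0.31 for microglia, 0.29 for interferon-response and -0.21 for synaptic genes (limma's camera adjusted p = 1.55e-07, 9.07e-05 and 0.00257). Without injured saline replicate 3 it was 0.20, 0.22 and -0.13, with 0.18 for reactive astrocyte genes (0.00633, 0.031, 0.0107 and 0.0107), without injured saline replicate 1 it was 0.22 for synaptic genes (0.00133), without injured MCI-186 replicate 3 it was 0.16 for them (0.0413), and without injured saline replicate 2 it was -0.20 for interferon-response genes (0.0296). The genes with the lowest p, none of which passed, were higher for Elf2 (1.24 ± 0.18, but 0.10 and 0.06 at its other 2 probes), Ly6e (0.47 ± 0.09, and 0.20 at its other probe), Rchy1 (0.38 ± 0.08), the drug efflux transporter gene Abcb1a (0.69 ± 0.14) and Or52n2e (at least 1.85-fold). They were lower for Cblc (-1.62 ± 0.31), the calcium-sensing receptor Casr (-0.55 ± 0.13), Ceacam4 (-0.96 ± 0.25), Traf6 (-0.50 ± 0.13) and Ly6c (at least 2.13-fold). Limma's 95% interval had a median half-width of 0.32 and excluded a 2-fold difference for 93.4% of genes. In simulated data with 200 of 9237 named genes changed, 80.0% of 2-fold and 40.0% of 1.5-fold changes were recovered. The simulation adjusted over those genes alone and not over unnamed probes, so the real test may recover fewer. The interval and the simulation both rest on 1 spread pooled over the 4 groups and may overstate the precision here, since injured pups varied more. The SD of the synaptic list was 0.35 and 0.39 in the injured groups and 0.05 and 0.01 in the controls. With only the injured groups fitted, 81 genes had an unadjusted p under 0.05. With array weights 611 genes passed, without control MCI-186 replicate 1 or injured saline replicate 3 just 1 did, and fry called 0 of the 29 lists.

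As a group, 13 measured myelin genes were lower in the injured pups given MCI-186 than in those given saline, with a median of -0.81 and all 13 differences below 0. Opalin was at -1.09 ± 0.30, Tspan2 at -0.40 ± 0.11 and Ermn at -1.09 ± 0.37. None passed over all genes and 8 were lower adjusted over the list alone, and limma's camera gave adjusted p = 1.98e-15, with adjusted p = 0.268 with an estimated correlation. The median was -1.23 without injured MCI-186 replicate 2 and -0.53 without injured saline replicate 1. Mean myelin levels relative to saline controls were 0.04, -0.54 and -0.43 in the injured saline pups and -1.23, -0.40 and -1.42 in the injured MCI-186 pups, so the groups overlapped. Beside them, striatum markers had a median of -0.13, with 1 of 10 lower adjusted over the list alone, Drd1 (-0.37 ± 0.10), and limma's camera adjusted p = 0.0273, with adjusted p = 0.819 with an estimated correlation. That call was lost without injured saline replicate 1 (adjusted p = 0.343) or injured MCI-186 replicate 1 or 3 (0.159 and 0.522), with medians of -0.07, -0.09 and -0.06, and the median was -0.20 without injured saline replicate 2.

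A further 4 lists passed limma's camera in this comparison and none held with an estimated correlation or without single pups, and no member passed over all genes or adjusted over the list alone. Immediate early genes had a median of 0.23, with Ier3 at 0.35 and Npas4 at 0.80 (limma's camera adjusted p = 0.00115, and adjusted p = 0.609 with an estimated correlation). Without injured MCI-186 replicate 2 their median was 0.09 and the adjusted p 0.486. Cholesterol synthesis genes had a median of 0.15 (limma's camera adjusted p = 0.00716, and adjusted p = 0.871 with an estimated correlation), and of 0.09, 0.09 and 0.05 without injured saline replicate 2 or 3 or injured MCI-186 replicate 2 (adjusted p = 0.0894, 0.658 and 0.711). Their median was 0.34 without injured saline replicate 1 and 0.23 without injured MCI-186 replicate 3. Hypoxia-inducible genes had a median of -0.10, with Adm at -0.55 (limma's camera adjusted p = 0.0273, and adjusted p = 0.609 with an estimated correlation). Without injured saline replicate 1 or 3 or injured MCI-186 replicate 1 or 2 the adjusted p was 0.133, 0.22, 0.159 and 0.0679, and the first of these gave a median of -0.06. Extracellular matrix genes had a median of -0.19, with Mmp9 at -0.93 (limma's camera adjusted p = 0.0273, and adjusted p = 0.871 with an estimated correlation), and of -0.02 without injured saline replicate 3, where the adjusted p was 0.501. It was -0.30 without injured MCI-186 replicate 3, and without replicate 2 it was -0.01 and the test turned upward (adjusted p = 0.97).

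The fourth comparison asked what MCI-186 changed in uninjured controls. A small set of genes differed, among them immediate early genes, which cells induce within minutes of stimulation and which were higher with MCI-186. The transcriptional regulators Ier2 and Btg2 rose by 1.16 ± 0.12 and 1.31 ± 0.15, and the matricellular Ccn1 by 1.94 ± 0.25 (SE, n = 3 pups per group, limma adjusted p of 0.00464, 0.00966 and 0.0185). In all, 11 of 9281 named genes passed limma's test, 5 higher and 6 lower, with 779 at an unadjusted p under 0.05, and 16 unnamed probes passed, 2 higher and 14 lower. The 3 values of one group lay wholly above those of the other for 26.9% of genes, against a chance share of 10%. For MCI-186 in injured pups this share was 4.07%, so it can lie well away from 10% in either direction.

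The other increases were of Aipl1, which was not well above background in saline controls and was at least 17.4-fold higher, and of the stress gene Gadd45g (0.80 ± 0.12, limma adjusted p = 0.045). Asb5, the chemokine gene Ccl22 and Fbxl7 were not well above background with MCI-186 and were at least 1.98-fold, 1.45-fold and 2.42-fold lower. Cilp fell by 1.10 ± 0.17 (0.71 at its other probe), Tent5c by 2.29 ± 0.31 and Tmem82 by 2.62 at a probe not well above background with MCI-186 (limma adjusted p of 0.045, 0.0238 and 0.0274), and by 2.11 at its other probe. For Cilp and Tmem82 the other probe was the brighter. With no filter on dim probes, where it was used, their limma adjusted p was 0.218 and 0.0935. The count of genes that passed was 5 without control MCI-186 replicate 1 and 7 without saline control replicate 1. Over 23 other settings the call of Cilp was lost in 20, of Gadd45g in 15, of Tent5c in 9, of Ccn1 in 7 and of Btg2 in 2, while over 22 settings Tmem82 lost it in 9, Fbxl7 in 4, Asb5 in 3, Ccl22 in 3 and Aipl1 in 1. Cilp lost its call without any single array other than control MCI-186 replicate 2 (limma adjusted p from 0.0534 to 0.185) and Gadd45g without any other than injured saline replicate 3 (0.0502 to 0.187). Tent5c lost it without saline control or control MCI-186 replicate 1 or 2 or injured saline replicate 2 (0.0523 to 0.118), Tmem82 without saline control replicate 1 or 2 or any control MCI-186 replicate (0.0862 to 0.118), and Ccn1 without any saline control or control MCI-186 replicate 2 or 3 (0.0523 to 0.0816). Without control MCI-186 replicate 1, the limma adjusted p was 0.0575 for Fbxl7 and 0.0543 for Ccl22, and without saline control replicate 2 that of Asb5 was 0.0515.

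Of 21 immediate early genes, 2 rose over all genes and 12 adjusted over the list alone, with a median of 0.62. Npas4 was at 2.08 ± 0.44 and Junb at 1.09 ± 0.24, neither of which passed over all genes (limma adjusted p of 0.141 and 0.145). The list passed limma's camera at adjusted p = 1.34e-13, with adjusted p = 0.0772 with an estimated correlation, and fry called this list alone of the 29 (limma adjusted p = 0.01). The 3 pups given MCI-186 had list means of 0.75, 0.83 and 0.69, above the saline controls at -0.19, 0.05 and 0.14. Glucocorticoid-responsive genes were lower, with a median of -0.29 and Ddit4 at -0.44, Map3k6 at -0.43 and Nfkbia at -0.34, none of which passed either way (limma's camera adjusted p = 0.00132, and adjusted p = 0.208 with an estimated correlation). Red blood cell genes were lower as well, by a median of -1.86, with 0 of 6 passing over all genes and 5 lower adjusted over the list alone (limma's camera adjusted p = 3.63e-05, and adjusted p = 0.55 with an estimated correlation). Epb42 was at -2.04 ± 0.58 and Hbb at -1.74 ± 0.63, and the means of the 6 genes were 0.61, 0.07 and -0.68 in the saline controls and -1.62, -1.63 and -1.20 with MCI-186.

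Myelin genes were higher in controls given MCI-186, with a median of 0.36 and Opalin at 1.19 ± 0.30 (0.38 at its other probe), the only member to pass adjusted over the list alone (limma's camera adjusted p = 4.14e-05, and adjusted p = 0.566 with an estimated correlation). Oligodendrocyte progenitor markers had a median of 0.15, with 3 of 8 higher adjusted over the list alone, led by Sox10 at 0.62 ± 0.11 (limma's camera adjusted p = 0.0252, and adjusted p = 0.71 with an estimated correlation). Without saline control replicate 2 or control MCI-186 replicate 2 the adjusted p was 0.109 and 0.0632, and the median was 0.07 without control MCI-186 replicate 1. Cholesterol synthesis genes had a median of 0.16 with no member passing either way (limma's camera adjusted p = 0.0171, and adjusted p = 0.816 with an estimated correlation), and adjusted p of 0.109 and 0.058 without the same 2 pups. Homeostatic astrocyte genes had a median of -0.12 with Aqp4 at -0.50 (-0.27 to -0.04 at its other 3 probes) and no member passing either way (limma's camera adjusted p = 0.0196, and adjusted p = 0.208 with an estimated correlation), or 0.158 without saline control replicate 3. Cell death genes had a median of 0.11, with Gadd45g higher both ways (limma's camera adjusted p = 0.0221, and adjusted p = 0.787 with an estimated correlation). Interferon-response genes had a median of -0.16, with 1 of 20 lower adjusted over the list alone (limma's camera adjusted p = 0.0338, and adjusted p = 0.816 with an estimated correlation). This was Rsad2, at -3.59 at a probe not well above background with MCI-186 and at -2.17 at its other probe. The cell death call was lost without saline control replicate 1 or 2 or control MCI-186 replicate 3 (adjusted p from 0.0594 to 0.101), its median was 0.07 without saline control replicate 3, and the interferon call was lost without saline control replicate 2 or 3 or control MCI-186 replicate 2 or 3 (0.0566 to 0.147).

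**Figure D3:**
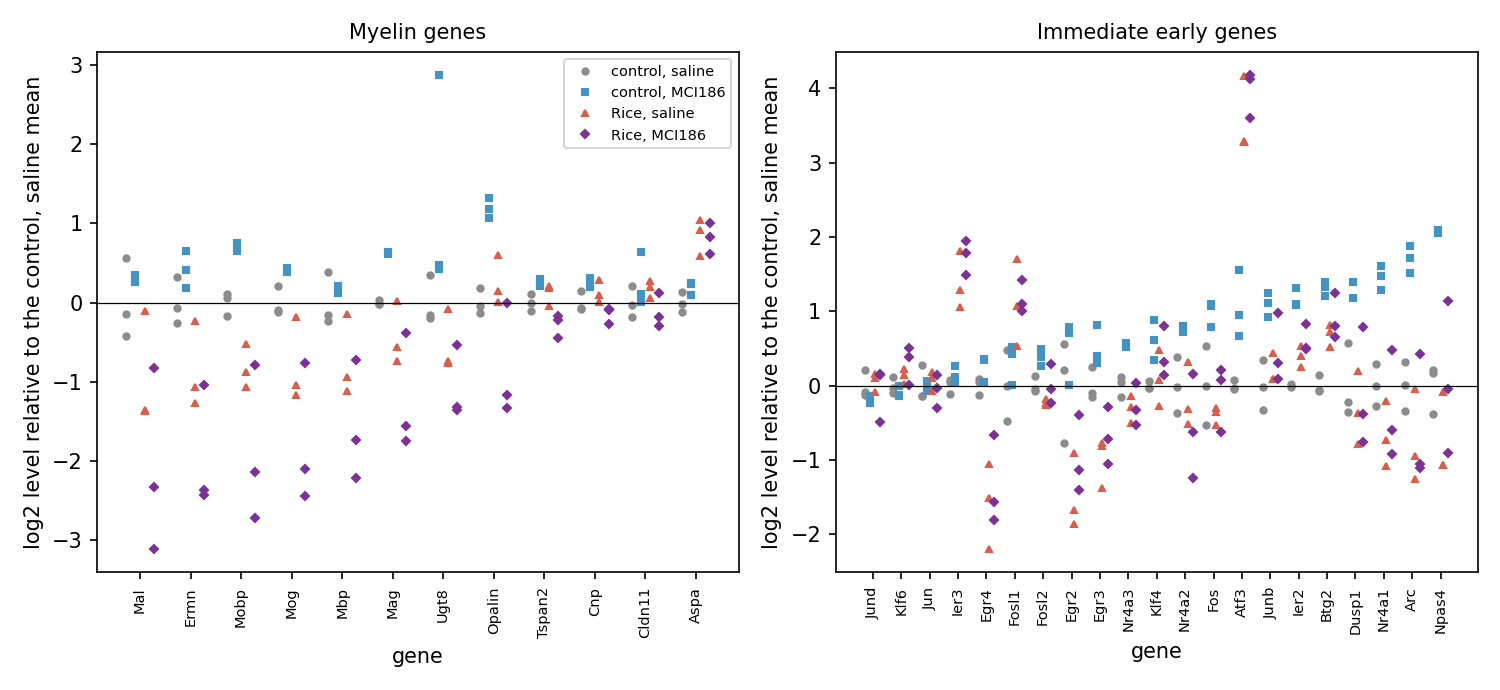
Log2 level of 12 of the 13 measured myelin genes (left) and of each measured immediate early gene (right) in each of the 12 pups relative to the mean of the saline controls, with 1 symbol per pup and 4 groups by colour and shape. The median difference between injured pups given MCI-186 and saline was -0.81 for the 13 myelin genes, and between controls given MCI-186 and saline it was 0.62 for the 21 immediate early genes.

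The last comparison tested whether the injury effect differed between the arms. The labels give a second injection for injured pups alone, so injury and the number of MCI-186 doses cannot be told apart in it. No single named gene passed. Myelin and immediate early genes had lower median injury effects with MCI-186 than with saline and passed limma's camera at its preset correlation, but not with an estimated one. Relative to saline controls, immediate early genes had list means of 0.76 in controls given MCI-186, 0.00 in injured saline pups and 0.22 in injured MCI-186 pups. Their difference thus came from the controls, and MCI-186 did not go with lower levels after injury. Myelin means were 0.49, -0.31 and -1.02 in the same order, so part of that difference also lay in the controls. The injury effect on Mobp was -0.82 in the saline arm and -2.58 in the MCI-186 arm (-1.04 and -2.42 at its other probe), and that on Arc was -0.75 and -2.28. Of 9279 genes limma called 0, with 368 at an unadjusted p under 0.05, and 3 unnamed probes passed. The genes with the lowest p were higher in the MCI-186 arm for Tent5c (2.51 ± 0.43), Cilp (1.36 ± 0.23, and 0.67 at its other probe), Asb5, Fbxl7 and the erythroid factor Nfe2. They were lower for Ppp1r14a (-0.98 ± 0.16), Drd1 (-0.83 ± 0.14), Ier2 (-0.95 ± 0.17), Cblc (-2.43 ± 0.44) and Aipl1, with limma adjusted p from 0.0678 to 0.224 over the 10. No size is given for Asb5, Fbxl7, Nfe2 and Aipl1, which were not well above background on any array of at least 1 group. The 13 myelin genes had a median difference of -1.38, 8 of them lower adjusted over the list alone (limma's camera adjusted p = 5.06e-17, and adjusted p = 0.208 with an estimated correlation). The exact permutation p for the list mean was 0.015, or 0.217 adjusted over the 29 lists, where a single list can reach no less than 0.145, so the adjusted test could not have passed for myelin alone. The 21 immediate early genes had a median of -0.51, with 2 lower adjusted over the list alone (limma's camera adjusted p = 2.71e-07, and adjusted p = 0.221 with an estimated correlation), and an exact permutation p of 0.165, or 0.746 adjusted. Red blood cell genes had a median of 1.49 beside them (limma's camera adjusted p = 0.00177, and adjusted p = 0.522 with an estimated correlation), or 0.59 without injured MCI-186 replicate 2, with an exact permutation p of 0.255, or 0.854 adjusted. In simulated data with 200 of 9237 named genes changed, 68.0% of 2-fold interactions and 14.0% of 1.5-fold ones were recovered. The simulation left unnamed probes out of the adjustment, so the real test may recover fewer. The 95% interval had a median half-width of 0.45. The simulation and the interval again rest on 1 spread pooled over the groups. The count was 265 with array weights, 5 without injured MCI-186 replicate 2, 2 without injured saline replicate 3 and 1 without saline control replicate 3 or injured MCI-186 replicate 3, and fry called none of the 29 lists.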

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

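The tests of slide differences, blood left in the tissue, size of the injury, slide and stress hormone exposure were chosen after the results were seen, while the reassignment of drug labels and the splits of the arrays were chosen before.

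For 6 of 29 gene lists, limma's camera at its preset correlation gave an adjusted p under 0.05 for the interaction between injury and MCI-186. Other lists passed the same test in some alternatives, so the split is not firm. Among them were interferon-response genes without saline control replicate 1 (median 0.16, limma's camera adjusted p = 0.0142) and cell death genes without injured saline replicate 2 (median -0.12, limma's camera adjusted p = 0.0154). An exact test of the list means over 200 reassignments of the drug labels can give a single list no adjusted p below 0.145 over 29 lists, so its adjusted values cannot decide for or against 1 list. Its exact permutation p was 0.015 for myelin (0.217 adjusted), 0.165 for immediate early (0.746), 0.255 for red blood cell (0.854), 0.07 for glucocorticoid-responsive (0.677), 0.18 for oligodendrocyte progenitor (0.746) and 0.13 for striatum genes (0.746). The difference in the median log2 injury effect was -1.38 for myelin genes (adjusted p = 5.06e-17, and adjusted p = 0.208 with an estimated correlation), and ran from -1.86 without injured MCI-186 replicate 2 to -0.95 without injured MCI-186 replicate 3. It was -0.51 for immediate early genes (adjusted p = 2.71e-07, and adjusted p = 0.221 with an estimated correlation). The immediate early and red blood cell differences lay mainly in the controls. Relative to saline controls, immediate early means were 0.76 in controls given MCI-186, 0.00 in injured saline pups and 0.22 in injured MCI-186 pups. Red blood cell means were -1.48, -0.76 and -1.01 in the same order. Red blood cell genes differed by 1.49, or 0.59 without injured MCI-186 replicate 2 (adjusted p = 0.00177, and adjusted p = 0.522 with an estimated correlation). Glucocorticoid-responsive genes differed by 0.29, or 0.17 without injured saline replicate 1 and 0.18 without injured MCI-186 replicate 3 (adjusted p = 0.0025, and adjusted p = 0.226 with an estimated correlation). Oligodendrocyte progenitor markers differed by -0.24 (adjusted p = 0.00349, and adjusted p = 0.41 with an estimated correlation). Their difference was -0.06 without injured saline replicate 3, -0.13 and -0.16 without control MCI-186 replicate 1 or 2, and -0.01 without injured MCI-186 replicate 2, where the call was lost (adjusted p = 0.167). Striatum markers differed by -0.23 (adjusted p = 0.0134, and adjusted p = 0.41 with an estimated correlation). Their call was lost without injured saline replicate 1 or injured MCI-186 replicate 3, at -0.01 and -0.10 (adjusted p = 0.0951 and 0.205), and the difference was -0.14 without saline control replicate 2 and -0.38 without injured MCI-186 replicate 2.

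Limma's interaction test also passed for 3 probes without a gene name, named here after their values were seen. Probe A_44_P432843 had a value of 3.95 (limma adjusted p = 9.72e-06) but was well above background in the saline controls alone of the 4 groups, so this value rests on signal at or near the floor and is not a measured size. Probe A_44_P143650 differed by 1.09 ± 0.11 (SE, limma adjusted p = 0.0166), was well above background on all 12 arrays, and was at -1.19 in controls given MCI-186 against saline. Probe A_44_P269407 had a value of 3.25 (limma adjusted p = 0.0166), which is not a measured size either. It was well above background in all 3 saline controls, 0 controls given MCI-186, 1 injured saline pup and all 3 injured MCI-186 pups.

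Injury changed much the same genes in both arms. Slide differences that arise independently on each slide are argued against by a Pearson correlation of 0.949 between the log2 changes of the arms over all named genes, which are not independent replicates, since the arms share no slide. The gap between the mean changes of microglia and red blood cell genes was 2.39 in the MCI-186 arm and 3.63 in the saline arm, against a pooled SD between pups of 0.769. Most of it is the microglia rise itself (2.86 and 2.87), seen before the test was chosen. Red blood cell genes moved by 0.47 and -0.76. Blood left in the tissue is thus argued against as the whole cause of the microglia rise, but a part in the MCI-186 arm stays open. The real grouping called 4931 genes in the saline arm and 5104 in the MCI-186 arm, and no other grouping of the same 6 arrays called any (highest other 0, so 1 of 10 splits in each arm), but 10 splits are too few for a share under 0.05. The labels name no batch shared by the injured slides, which were scanned in places 2 and 4, with the control slides in places 1 and 3. Injury itself, which the design names, remains as the hypothesis that the comparison was planned to test.

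Myelin genes had a lower median injury effect in the MCI-186 arm and a median difference below 0 between injured pups given MCI-186 and saline. A larger fall of neuronal genes as the whole cause is argued against in these pups. The myelin difference was -0.73 (SE 0.196) after adjustment for the synaptic and pan-neuronal genes of each pup, against -0.71 before. The neuronal list differed by just 0.02 between the injured groups, so the adjustment could change little. That difference turned on single pups, with a median of -0.21 without injured MCI-186 replicate 2. Other sides of the injury were not measured, so a larger injury as such stays open. A chance assignment of pups stays open. The interaction of the list mean was as large in 3 of 200 reassignments of the drug labels (exact permutation p = 0.015), or 0.217 adjusted over 29 lists, where a single list cannot go below 0.145. The adjusted test could therefore not have passed for myelin alone and decides nothing. The share for this list alone set too low a bound, because myelin was picked as the lowest of 29 lists, and heat shock proteins also reached 3 of 200. With 0 groups on more than 1 slide, slide and treatment cannot be told apart, and an effect of MCI-186 on myelin transcripts may be part of the difference but is untested. In the interaction, the second injection given to injured pups alone cannot be told apart from injury either.

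Immediate early genes were higher in controls given MCI-186 by a list mean of 0.76, against a pooled SD between pups of 0.134. Glucocorticoid-responsive genes, which stress hormone exposure was predicted to raise, had a mean difference of -0.23 with a pooled SD of 0.073. They gave no sign of such exposure at collection but cannot exclude it. The same slides are compared, and the list's call did not hold with an estimated correlation. Slide cannot be told apart from the treatment, with 0 groups on more than 1 slide, and red blood cell genes differed between the same groups by a median of -1.86. The real grouping of the 6 control arrays called 11 genes and the highest of the others 0, so 1 of 10 splits did as well, and 10 splits are too few for a share under 0.05. An effect of the drug or a difference in handling or collection between the groups may underlie the difference, and neither was tested.

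For MCI-186 in injured pups, the real grouping called 0 genes, which any split reaches, so the share of 10 of 10 splits carries no information, and 10 are too few for a share under 0.05. The highest of the others called 1473 genes, with injured saline replicates 1 and 2 and injured MCI-186 replicate 2 on one side, which points to a structure of the samples other than the treatment. On the first principal component, which set injured pups apart from controls, these pups lay at 39.6, 55.4 and 30.4. The other injured pups lay further from the controls, at 82.1, 74.5 and 74.7. For the interaction the real count was also 0, which all 100 of 100 drawn reassignments out of 200 reach by construction, so the share says nothing for or against chance. The highest other called 6.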

How the results depend on the processing

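Normexp on median signals and the fit without the least correlated array of each group were chosen after the data were seen, and all other alternatives before. The counts of injury genes stayed within 1.5 times of 4931 and 5104 in every alternative run, from 3848 to 6110 in the saline arm and from 4004 to 7393 in the MCI-186 arm. Over all alternatives, named genes of the injury comparisons kept their direction and side of the threshold in 5959 of 6044 cases (55 lost the call, 30 gained it, 0 reversed), and of the other comparisons in 5680 of 5855 (73, 102 and 0). Gene lists did so in 1314 of 1390 injury cases (57, 19 and 0) and in 1866 of 2056 others (99, 72 and 19). Cases that passed neither in the main fit nor in the alternative count as kept here. Outside the injury comparisons most cases were of this kind, so these shares do not measure how firm the calls were. All 73 lost gene calls there fell on the 11 genes called for MCI-186 in controls. The interaction called 2 genes with quantile normalization and 1 each with no filter on dim probes, the stricter filter, normexp on median signals and without the least correlated arrays. MCI-186 in controls called 4 genes with normexp on median signals, all higher, against 5 higher and 6 lower, and 19 with only the groups of the contrast, where the interaction has no value. With array weights, which ran from 0.23 for injured MCI-186 replicate 2 to 6.10 for replicate 1, MCI-186 called 611 genes in injured pups and 550 in controls, the interaction 265, and the slope between the arms was 1.07. The direction of the list test reversed there, with medians of 0.27 for reactive astrocyte and 0.45 for interferon-response genes in injured pups and 0.40 for microglia and macrophage markers in the interaction. Without the least correlated array of each group, MCI-186 called 1 gene in injured pups and 5 in controls, and the slope was 1.13. Reversed medians for MCI-186 in injured pups were then 0.34 for reactive astrocyte, -0.21 for inhibitory neuron, -0.41 for synaptic, 0.042 for extracellular matrix, 0.51 for interferon-response and -0.075 for cholesterol synthesis genes, and in the interaction 0.42 for microglia and -0.36 for synaptic genes. With single arrays left out, where the remaining pair is assumed to vary like the other groups, MCI-186 called 0 to 1 genes in injured pups and 5 to 16 in controls, the interaction 0 to 5, and the slope ran from 0.897 to 1.07. List medians for MCI-186 in injured pups then ran from -0.20 to 0.18 for reactive astrocyte, from -0.21 to 0.22 for synaptic, from -0.30 to -0.0062 for extracellular matrix and from -0.20 to 0.29 for interferon-response genes, and in the interaction from -0.17 to 0.22 for microglia and from -0.18 to 0.24 for synaptic genes. Of 59 list calls, 0 held when camera estimated the correlation. Fry, used here to test for a shift of a list in 1 direction and not against other genes, called 50 of 145, among them 39 of the 59. Apart from fewer samples or genes, the cause was not tested for any of these. With the replicate number as a block, MCI-186 in controls called 6 genes, injury 4653 and 4834, and the interaction and MCI-186 in injured pups 0. Pups of the same number did not deviate together, with correlations from -0.283 to 0.537 over 18 pairs and 2 above 0.1, so the number was not taken as a pairing. The authors' values gave 4924, 5107, 0, 11 and 0 genes in the order of the comparisons. The mean of a gene's probes, which needs no choice of probe, gave 5040, 5220, 0, 11 and 0 genes and 59 list calls. The medians of all genes moved by less than 0.1 between scalings. Not run were normexp on mean signals, a column not used here, and the slide as a block, since each group lies on its own slide. Signal over background limits the dim genes, since 64950 values were set to the floor and the lowest signal well above background lay between -6.04 and -5.21 on the log2 scale, relative to the 75th percentile of each array.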

Other observations

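No hypothesis was tested in this part, and none of its tests was chosen after the result was seen. Several gene lists written before the data were examined held members that moved in opposite directions after injury. Of 15 heat shock genes, 4 rose and 5 fell in the saline arm and 4 and 3 in the MCI-186 arm, or 4 and 6, and 4 and 3, adjusted over the list alone (limma's camera adjusted p = 0.939 and 0.665). The small heat shock protein genes Hspb1 and Hspb8 rose by 3.02 ± 0.33 and 2.53 ± 0.24 in saline pups and by 3.43 ± 0.33 and 2.75 ± 0.24 in MCI-186 pups, and the co-chaperone gene Bag3 by 1.60 ± 0.18 and 1.92 ± 0.18. The cytosolic chaperone gene Hsp90aa1 fell by 0.85 ± 0.27 and 0.87 ± 0.27. Of 24 hypoxia-inducible genes, 7 rose and 7 fell in each arm, or 9 and 8, and 8 and 7, adjusted over the list alone (limma's camera adjusted p = 0.445 and 0.406). Hexokinase 2, Hk2, rose by 2.26 ± 0.33 in the saline arm and was at least 4.07-fold higher in the MCI-186 arm, and adrenomedullin, Adm, rose by 1.66 ± 0.22 and 1.38 ± 0.22. The vascular growth factor gene Vegfa fell by 0.68 ± 0.14 and 0.93 ± 0.14, and the glycolytic gene Aldoa by 0.73 ± 0.12 and 0.66 ± 0.12.

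Vascular, secreted and hormone-responsive genes were also mixed. Of 14 endothelial markers, 3 rose and 4 fell in the saline arm and 5 and 4 in the MCI-186 arm, also adjusted over the list alone (limma's camera adjusted p = 0.687 and 0.944). The adhesion gene Pecam1 rose by 0.97 ± 0.16 and 1.28 ± 0.16, while the blood-brain barrier transporter genes Slco1c1 and Mfsd2a fell by 1.11 ± 0.13 and 1.14 ± 0.22 in saline pups and by 1.08 ± 0.13 and 1.14 ± 0.22 in MCI-186 pups. Of 18 growth factor and neuropeptide genes, 7 rose and 6 fell in the saline arm and 7 and 4 in the MCI-186 arm, or 7 and 6, and 7 and 5, adjusted over the list alone (limma's camera adjusted p = 0.43 and 0.234). Gdf15 rose by 3.32 ± 0.42 and 2.69 ± 0.42, galanin, Gal, by 3.21 ± 0.49 and 2.52 ± 0.49, Igf1 by 2.39 ± 0.20 and 2.21 ± 0.20 and Fgf2 by 2.16 ± 0.27 and 2.27 ± 0.27, and neuregulin, Nrg1, fell by 1.05 ± 0.21 and 1.25 ± 0.21. Of 11 glucocorticoid-responsive genes, 4 rose and 3 fell in the saline arm and 5 and 3 in the MCI-186 arm, also adjusted over the list alone, with Cebpd 2.58 ± 0.21 and 2.89 ± 0.21 higher. That list passed limma's camera in the MCI-186 arm alone (adjusted p = 0.303 and 0.0325, the latter adjusted p = 0.284 with an estimated correlation), with a median of 0.24 there, or 0.10 without injured MCI-186 replicate 3, and limma's camera on the interaction gave adjusted p = 0.0025, or adjusted p = 0.226 with an estimated correlation (exact permutation p = 0.07, or 0.677 adjusted). Of 9 xenobiotic response genes, 4 rose and 2 fell in each arm, also adjusted over the list alone, with the quinone reductase gene Nqo1 1.16 ± 0.23 and 1.13 ± 0.23 higher and the transporter gene Abcc2 at -0.57 ± 0.13 in saline pups (limma's camera adjusted p = 0.303 and 0.261).

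The direction of limma's camera differed from the sign of a list's median or mean in several cases, none of them called. After injury these were immediate early genes, heat shock proteins and growth factors in the saline arm and heat shock proteins, endothelial markers and growth factors in the MCI-186 arm. For MCI-186 in injured pups they were antioxidant, T cell, reactive astrocyte, inhibitory neuron, choroid plexus, growth factor and interferon-response genes, for MCI-186 in controls antioxidant and excitatory neuron genes, and for the interaction antioxidant, T cell, excitatory neuron, growth factor and xenobiotic response genes. Injured pups of one group stood further apart than controls on the first principal component, at 39.6, 55.4 and 82.1 with saline and 74.5, 30.4 and 74.7 with MCI-186, against -63.1 to -55.7 in the 6 controls. The log2 changes by MCI-186 in injured pups and in controls correlated at 0.115 across named genes, which are not independent replicates.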
